A study of Mus musculus with 1392 samples.

How the data were processed

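Single-cell ATAC-seq was run on sorted bone marrow cells with a plate-based protocol, per the labels' protocols, and each sample is 1 cell. The deposited table holds raw counts per peak and cell, whole numbers that the authors did not normalize, as the values show. The submitters' processing notes name Trim Galore, FastQC, Bowtie2, SAMtools and Picard without versions, and the mouse build mm9. The peak caller, whether peaks were called on pooled cells, whether reads or fragments were counted, any shift of cut sites and the filters on cells are not given in the sources used here. If peaks were called on pooled cells, the age with more counts had more weight in which regions became peaks. Duplicate reads or reads with several matches that were kept would raise counts at some peaks, and 77.7% of the nonzero entries were 1 while the highest was 209. Peaks were 199 to 3907 bp wide, with a median of 417 bp. Positions are given as the table names the peaks, and whether its starts count from 0 or 1 is not stated.

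Every column matched the title of 1 sample, and no 2 cells had identical columns. Groups and set numbers came from the titles. Of 115295 peaks, 68 had no count, and 94.6% of all entries were 0. Counts were summed per set and tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr with a minimum count of 10, robust dispersion and the quasi-likelihood test for old against young. A peak was called at a Benjamini-Hochberg adjusted p under 0.05. The common dispersion was 0.0248. Standard errors of log2 fold changes were taken as the fold change over the square root of the F statistic. The totals per set ran from 1159957 to 4181770 counts, and the median called peak rested on 99 counts over all sets when higher in old and on 166 when higher in young. The 95% intervals of fold changes are 1.96 of these standard errors on either side, and the floor covers counting error only.

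The edgeR step was tested on simulated counts for the 58167 tested peaks. It recovered 17% of 100 peaks changed by 1 on the log2 scale and 82% of 100 changed by 2, with median fitted sizes of 1.00 and 2.02, and called 4 unchanged peaks. Changes of the smaller size would therefore mostly be missed at this depth. All simulated peaks were given the common dispersion. The simulation therefore does not test peaks that vary more between sets, nor how often such peaks are called falsely. Clustering was tested on 300 simulated cells of 1 depth, a part of which had 300 peaks raised 8-fold. Each cluster was given the state of most of its cells, and 100% of cells had that state. A state split over several clusters does not lower this score. The cells of the data varied in depth, so the simulation does not test clustering across depths.

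Cells were clustered on binarized peaks found in at least 1% of cells, with TF-IDF weights, truncated singular value components 2 to 15, 15 neighbours and Leiden resolution 0.5 (scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9). No doublet caller was run. For measures that move with depth, each cell was thinned to 1906 counts, the 10th percentile of counts over all cells. This left out 4, 5, 84, 13 and 34 cells of young 1, young 2, old 1, old 2 and old 3. Values per set were compared by an exact two-sided permutation of the set labels over 10 splits, which cannot go below 0.1. Classes of peaks were compared with Fisher's exact test in scipy 1.17.1.

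The peaks named are, in each direction, the 10 with the smallest p among those called with every old set on one side of every young set. This rule, the main tests and most alternatives were fixed before the data were examined. Tests and alternatives chosen later are named as such where they are given. The alternatives concern the test, scaling, count filter, binarized counts, cell filter, thinning, equal numbers of cells, sex chromosomes, threshold, the set number as a block, each set left out in turn, and the resolution, components and peaks of the clustering. The gene table given here is of assembly GRCm38.p6, which differs from mm9, so peaks were not assigned to genes. Gene lists, genes of the sort and cell type markers were not analysed here.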

Results

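Chromatin accessibility was measured by single-cell ATAC-seq, in which a transposase cuts open DNA and adds sequencing adapters to it, in haematopoietic stem cells sorted from the bone marrow of young and old C57BL/6 mice. The sorted cells were positive for Sca-1, Kit, CD150 and Vwf and negative for lineage markers, CD48 and CD34. Vwf encodes von Willebrand factor, a clotting protein, and marks stem cells inclined towards the platelet lineage. The question was whether the makeup of this population changes with age. The table held counts for 115295 peaks in 1392 cells, of which 332 were young and 1060 old. The cells formed 5 numbered sets, with 181 cells in young 1, 151 in young 2, 306 in old 1, 380 in old 2 and the rest in old 3. Nothing in the labels says whether a set is an animal, a pool or a plate, so each set was taken as 1 replicate and p-values measure only the spread between sets, which may be technical. Each set holds cells of 1 age, so age and the preparation of a set cannot be told apart.

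Depth differed among sets of the same age. The sum of counts was 1159957 in young 1, 2589894 in young 2, 4181770 in old 1, 2125677 in old 2 and 1640887 in old 3. The median count per cell was 6133 in young 1, 11807 in young 2, 9623 in old 1, 4434 in old 2 and 3604.5 in old 3. The log2 ratio of old to young was -0.61 for these medians, which was within the spread between sets (exact two-sided permutation p = 0.4, where 0.1 is the smallest value that 2 sets against 3 allow). In old 1, 27.8% of cells had under 2000 counts, against 2.21% to 9.89% in the other sets.

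Old and young cells differed in accessibility at 1844 of 58167 tested peaks. Of these, 808 were more accessible in old cells and 1036 in young cells (edgeR quasi-likelihood test on counts summed per set, Benjamini-Hochberg adjusted p under 0.05). Which age held more of the calls was not stable. The division turned to 1051 higher in old and 770 higher in young with library totals in place of composition factors, to 845 and 817 with binarized cells, and to 762 and 592 without old 1. It leaned further to young with DESeq2, with 113 higher in old and 310 in young, with thinned cells, with 69 and 151, without old 2, with 385 and 690, and without young 2, with 621 of 989 higher in young. The median log2 fold change was 1.92 among peaks higher in old and -1.48 among peaks higher in young. The medians are the same with the 22 peaks without a count in young cells and the 1 without a count in old cells at a floor of 3 counts over the group, which follows from each of these lying beyond the median at that floor as well. The sets of the 2 ages did not overlap in 17457 of the 56323 peaks that were not called, where chance alone gives 20%, while among called peaks the test itself selects for separation. Of the called peaks, 3 higher in old and 34 higher in young had 50% or more of their counts in 5 cells. DESeq2 called 423 peaks, and the count was 989 without young 2, 1075 without old 2 and 776 without old 3.

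The peak on chromosome 2 at 107071540 to 107072298 (mm9, as the table names it) had the smallest p among those higher in old. It had 53.3 ± 17.9 CPM (counts scaled to the TMM-adjusted total of tested peaks) in old sets (SD, n = 3) against 1.40 ± 0.565 in young sets (SD, n = 2), a log2 fold change of 5.01 with a standard error of 0.46 (edgeR adjusted p = 2.21e-11). A peak on chromosome X at 7524283 to 7525653 had 72.2 ± 18.5 CPM in old and 15.6 ± 5.19 in young sets, a log2 fold change of 2.13 with a standard error of 0.27 (edgeR adjusted p = 8.71e-08). On chromosome 1, the peak at 15668935 to 15669490 had a log2 fold change of 4.09, from 1.17 ± 0.247 in young to 22.7 ± 7.41 CPM in old sets. The strongest signal of this group lay on chromosome 11 at 115880192 to 115882214, with 161.5 ± 25.2 CPM in old against 52.2 ± 0.846 in young sets and a log2 fold change of 1.63. The other 6 peaks named by the same rule lay on chromosome 11 at 118465410 (3.97) and 86395443 (2.15), on chromosome 9 at 68788879 (2.90), on chromosome 3 at 98917110 (2.495), on chromosome 10 at 4105090 (3.63) and on chromosome 6 at 81688057 (4.04), with the log2 fold change in brackets. These peaks were 483 to 2022 bp wide, and no more than 9.59% of the counts of any of the 10 came from its 5 highest cells. Young counts were few for 5 of them, with 5 in all at 107071540 and at 4105090 and 4 at 81688057, at 15668935 and at 118465410. Without young 2 the log2 fold change was 5.64 at 107071540, 3.89 at 68788879, 2.83 at 86395443 and 2.75 at 4105090, and 4.41 at the last without young 1. At 81688057 young 2 held every young count, so no fold is given without it. Without very shallow or deep cells it was 3.64 at 68788879 and 4.68 at 81688057. The peak on X at 7524283 had a log2 fold change of 1.51 when each cell was counted once per peak and of 2.89 with cells thinned to 1 depth, where 5 young counts were left. In thinned cells no young count was left at 107071540, 81688057 and 15668935. Against a floor of 3 counts over the young cells, these were 12.1-fold, 5.33-fold and 4.52-fold higher in old. The lower Clopper-Pearson 95% limits of the ratios, which use no floor, were 9.63, 4.16 and 3.50. At 86395443, 1 young count was left, and the ratio of counts per cell was 21.9 with a Clopper-Pearson 95% interval of 3.79 to 879, which covers counting error only.

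Among peaks more accessible in young cells, the smallest p belonged to one on chromosome 16 at 24583388 to 24584104. It had 149.04 ± 23.4 CPM in young sets (SD, n = 2) and 16.8 ± 1.48 in old sets (SD, n = 3), a log2 fold change of -3.16 with a standard error of 0.22 (edgeR adjusted p = 7.14e-16). The peak on chromosome 2 at 66027197 to 66027593 had 482.4 ± 21.5 in young and 61.4 ± 16.0 in old sets, a log2 fold change of -2.95. Of the 10 peaks named, 8 were only 217 to 265 bp wide. They lay on chromosome 7 at 145785098, chromosome 17 at 63086805, chromosome 5 at 80929805 and 112933211, chromosome 13 at 111393164, chromosome 2 at 28039997 and 4437011, and chromosome 15 at 21586154, with log2 fold changes from -3.31 to -2.43. These 8 held 1.83 to 6.21 counts per cell that had any. Folds of these 10 peaks were smaller when each cell was counted once per peak. Those on chromosome 13 and chromosome 15 no longer passed, with log2 fold changes of -0.80 and -0.64 (edgeR adjusted p = 0.296 and 0.473). The others passed, with -1.09 at 80929805, -1.43 at 66027197, -1.45 at 145785098, -1.53 at 63086805, -1.55 at 4437011, -2.22 at 24583388, -2.504 at 112933211 and -2.80 at 28039997.

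**Figure D1:**
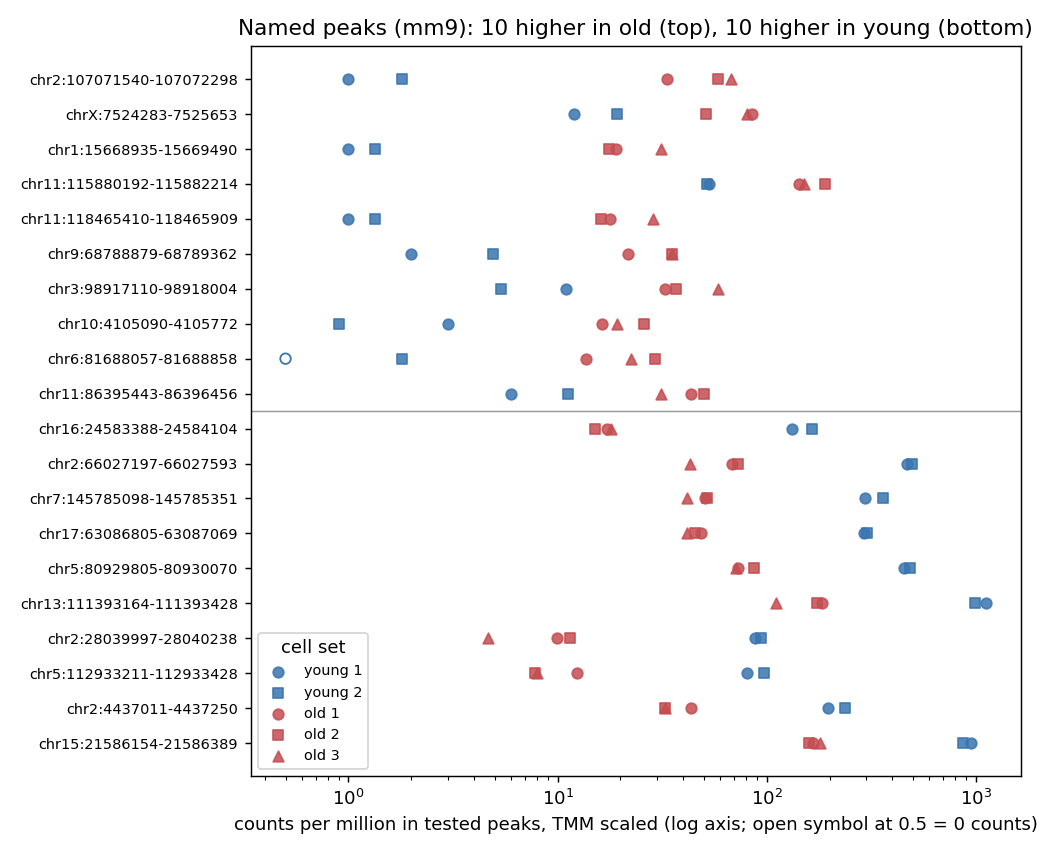
CPM (log axis) in each of the 5 cell sets for the 10 named peaks higher in old cells and the 10 higher in young cells, 1 symbol per set. The old sets lie to the right of both young sets in the upper 10 rows and to the left in the lower 10.

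Peaks higher in old cells also lay side by side on chromosome X between 7436290 and 7548993, a region singled out after its values were seen. Of 11 tested peaks there, 8 were called, with log2 fold changes from 1.39 to 2.13. The peak at 7475881 to 7477070 in the same region had a log2 fold change of 0.42 with a 95% interval of -0.13 to 0.98 and was not called. All 11 together held 415.4, 300.1 and 396.1 CPM in old 1, old 2 and old 3, and 165.5 and 134.4 in young 1 and young 2, here relative to all counts of the set.

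**Figure D2:**
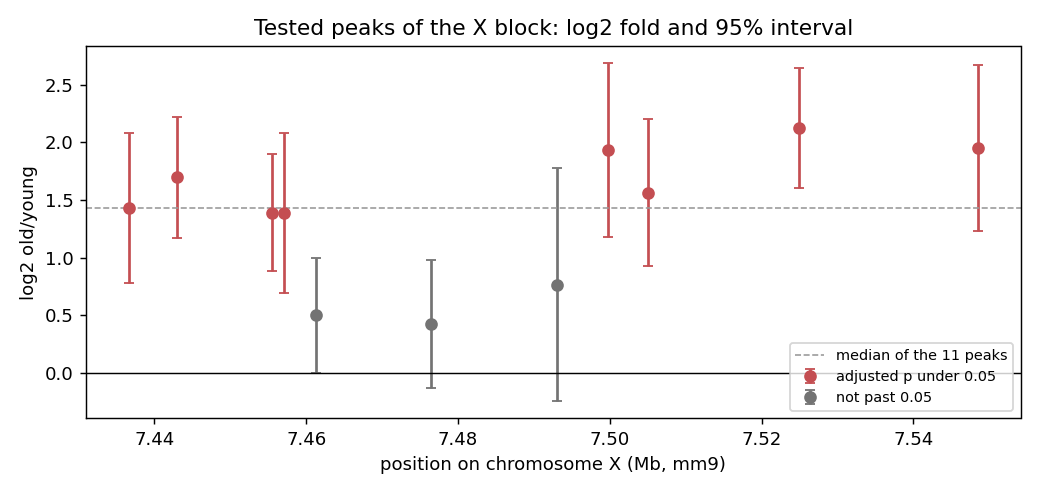
Log2 ratio of old to young against position on chromosome X (Mb, mm9) for the 11 tested peaks of the region, with 95% intervals. The 8 called peaks lie between 1.39 and 2.13, and 3 peaks in the middle did not pass.

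Peak width and signal differed by direction. Of 3358 tested peaks under 300 bp, 6.55% were higher in young and 1.28% in old cells. The other widths showed no steady order. The shares higher in young and in old were 1.90% and 1.77% of 19881 peaks of 300 to 600 bp, 1.22% and 1.69% of 20800 peaks of 600 to 1000 bp, and 1.31% and 0.432% of 14128 wider peaks. With the peaks under 300 bp left out before fitting, which was chosen after the data were seen, 757 peaks were higher in old and 774 in young cells. In the top 10% by mean counts, 4.56% of 5817 peaks were called, against 3.02% of the other 52350 (Fisher's exact test, two-sided, p = 1.76e-09, adjusted p = 2.11e-09 over 6 such tests). The 2 directions parted there. Peaks higher in young made up 4.16% of the top 10% and 1.52% of the rest, and peaks higher in old 0.395% and 1.4995%. Fisher's test treats peaks as independent, which neighbouring peaks are not. Peaks with more counts also give the edgeR test more power, which may add to the share of calls in the top 10%. More power would raise the share in both directions, while that of peaks higher in old was lower there. These values argue against power alone for the parting of the 2 directions.

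Chromosome shares were close between ages except on chromosome Y, which carried few counts. The sets of the 2 ages did not overlap on 8 of 21 chromosomes, against 4.2 expected by chance, and no chromosome passed adjustment (smallest adjusted exact permutation p = 0.42). The log2 ratio of old to young was -0.05 on chromosome 5, -0.06 on chromosome 8, 0.05 on chromosome 12 and -0.08 on chromosome X. Chromosome Y carried 404 counts in all over 13 peaks. Its share was 0.00638% ± 0.000483 in young (SD, n = 2) and 0.00208% ± 0.000561 in old sets (SD, n = 3), a log2 ratio of -1.62 (exact two-sided permutation p = 0.1, adjusted 0.42).

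Peaks called in alternate cells of each set were counted in the cells left aside, with every cell thinned to 1906 counts. The 213 peaks called higher in old from those cells held a mean of 8.28, 9.64 and 10.6 counts per cell in old 1, old 2 and old 3, with an SD over cells of 2.93, 3.38 and 4.13. In young 1 and young 2 they held 3.57 and 3.33 counts per cell, with an SD of 2.25 in each. An old cell had more of these counts than a young cell in 93.1% of pairs, with a tie counted as 0.5. The 370 peaks called higher in young held 58.9 and 54.0 counts per cell in young 1 and young 2, and 17.6, 20.8 and 20.3 in old 1, old 2 and old 3. The SD over cells was 26.5 and 24.2 in the young sets and 6.90, 11.02 and 30.3 in the old sets. This list was uneven across cells, most of all in old 3, where its variance over mean was 30.7 times that of lists matched on counts. Without thinning the first list took 0.187% and 0.167% of counts in the young and 0.399%, 0.478% and 0.527% in the old sets, and the second 3.07% and 3.16% in the young and 1.02%, 1.13% and 1.06% in the old sets. Both parts of the cells come from the same sets, so these values carry any difference between preparations too.

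**Figure D3:**
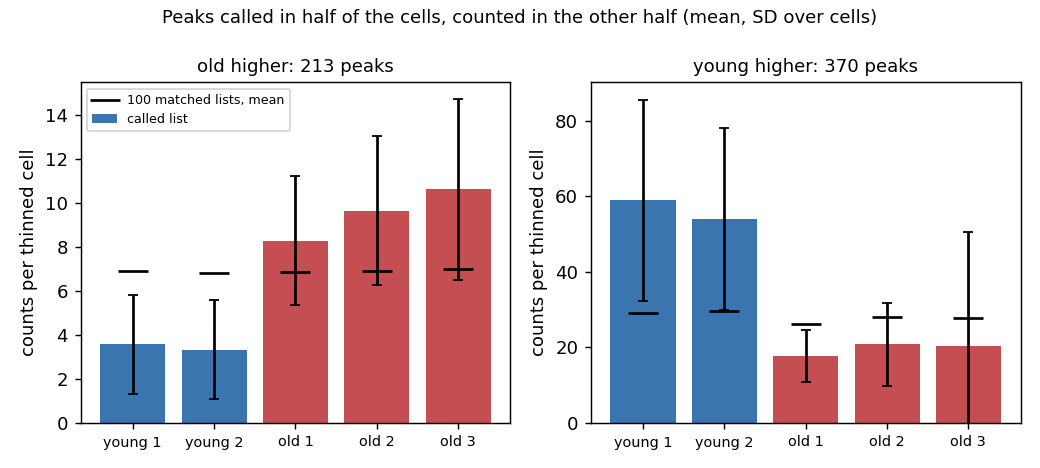
Mean counts per thinned cell in each cell set, with bars for the SD over cells, for the 213 peaks higher in old and the 370 higher in young that were called in the other cells. Horizontal marks give the mean of 100 lists matched on counts. In the old sets the first list lies at 8.28 to 10.6 counts, against 3.33 and 3.57 in the young sets.

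Cell states were compared by clustering the cells. Clustering on all peaks uses those that differ with age, so shares are given for cells clustered without the 1844 called peaks, which formed 7 clusters. This does not remove the difference between ages. The ages did not overlap in 17457 of the 56323 peaks that were not called, where chance alone gives 20%. The shares are therefore no comparison of cell states apart from that difference. Cluster 2 held 46.4% of young 1 and 70.2% of young 2 cells but 6.86%, 6.58% and 2.41% of old 1, old 2 and old 3 cells. Its mean was 58.3% ± 16.8 in young (SD, n = 2) and 5.28% ± 2.49 in old sets (SD, n = 3). Cluster 1 held 9.55% ± 1.33 of young and 25.2% ± 0.713 of old cells. Each difference had an exact two-sided permutation p of 0.1, the smallest possible, and an adjusted p of 0.35. Cluster 6 held 42.8% of old 1 and at most 4.74% of any other set, and its cells had a median of 21482.5 counts. When cells were also thinned to 1 depth, an alternative chosen after the data were seen, 4 other clusters formed and the largest difference in share was -15.01 percentage points (exact permutation p = 0.3). The sets of the 2 ages still did not overlap in 2 of these 4. One held 32.8% and 25.3% of the young sets and 39.6%, 40.3% and 41.5% of the old sets, and the other 6.21% and 2.05% of the young and 12.2%, 8.17% and 9.71% of the old sets (exact permutation p = 0.1 for each, the smallest possible, adjusted 0.2). Chance alone keeps the ages apart in 20% of clusters. Clusters are given by number, since no gene annotation of the build was used.

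Whether old cells differed more from one another depended on what was made equal. With each cell thinned to 1906 counts, the mean Jaccard distance between pairs of cells, 1 minus the share of detected peaks they have in common, was 0.973 in young 1 and 0.974 in young 2. It was 0.977, 0.977 and 0.978 in old 1, old 2 and old 3. The difference of 0.0035 had an exact two-sided permutation p of 0.1, the smallest that 5 sets allow, and so could not pass 0.05. With each cell thinned to 1720 detected peaks in place of counts, which was chosen after the data were seen, the sets of the 2 ages overlapped, with 0.977 and 0.981 in the young and 0.982, 0.979 and 0.9796 in the old sets (exact permutation p = 0.6). Without thinning they also overlapped, with 0.938 and 0.896 in the young and 0.931, 0.951 and 0.960 in the old sets. With equal detected peaks, young 2 and old 1, which had the highest median counts per cell, had the largest distances. Depth may therefore still enter that measure.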

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

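The alternatives without peaks under 300 bp, without peaks that rest on 5 cells, with 50 components computed, with cells thinned to equal detected peaks, and those that combine 2 choices were chosen after the data were seen. Against 1844 called peaks, DESeq2 called 423, a minimum count of 30 called 769 among 22788 peaks tested, thinned cells 220 among 13854 tested, equal numbers of cells 866, and a threshold of 0.01 left 840. Fewer counts or peaks, or a stricter limit, enter each of these except DESeq2. It was run on 115227 peaks without the count filter, so both the test and the peaks differed. The cause of its lower count was not tested, and of its calls 422 were shared with the 1844. Leaving out 1 set gave 776 to 1641 calls, with 989 without young 2, 1075 without old 2 and 776 without old 3. A young set left out leaves 1, assumed to vary like the old sets. With no filter 2583 peaks were called. Set numbers are shared by both ages, but deviations from the group means correlated at -0.0758 for young 1 with old 1 and at -0.000706 for young 2 with old 2, so they were not taken as pairs. With the set number as a block 1102 peaks were called, 470 higher in old and 632 in young. Alternatives reuse the counts from which the 20 named peaks were picked by p, so their values there are no independent support. A setting in which a peak was not tested gives no value. The 20 named peaks kept their direction in all 401 values under alternatives and passed in 399, the exceptions being 2 peaks under binarized counts (log2 fold changes -0.80 and -0.64).

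The largest difference in a cluster's share was -34.6 percentage points with all peaks, and from -65.2 with thinned cells to -15.01 with thinned cells and without the called peaks. With 50 components computed in place of 30 it was -62.97, so the clusters depend on that choice. Leaving out 1 set gave -47.4 to -32.7 points. The edgeR test on cells per cluster, run on the 6 clusters from all peaks, whose numbers differ from those without the called peaks, passed for 4, with log2 ratios of 2.28, -1.89, 3.21 and -2.32 for clusters 1, 2, 4 and 5 (adjusted p = 0.0212, 0.0237, 0.0340 and 0.0237). The exact permutation cannot pass, so these calls rest on the model. These 6 clusters were also formed with the called peaks, which were picked for differing between the ages. A difference in their shares is thus partly built in, and the 4 calls are no independent support. The edgeR test was not run on the clusters without the called peaks. The log2 ratio of peaks detected per cell was -0.48, and leaving out 1 set gave -0.98 to 0.031, the latter without young 2, while that of counts per cell ran from -1.16 to -0.06. Chromosomes without overlap between ages numbered 8, 6 with binarized counts, and 9 to 13 with 1 set left out, the latter without young 2, where chance alone also keeps fewer sets apart more often. The difference in Jaccard distance was 0.0012 with equal detected peaks, where the ages overlapped, and ran from 0.0026 to 0.0073 in the others, the latter on the scale of 1 minus Spearman correlation. With the top 20% by mean counts in place of the top 10% the log2 odds were 0.37 against 0.62. Alternatives for gene lists were not run, since no genes were assigned.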

Other observations

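Tests of the equal gain on X, of the other splits, of runs of called peaks and of pairs of cells were chosen after the results they concern were seen. Called peaks lay close together along the genome. Of the peaks higher in old, 112 had another such peak within 50000 bp, against a mean of 54.9 in 1000 shuffles of the calls among tested peaks (permutation p = 0.001, the smallest these shuffles can give). Of the peaks higher in young, 231 did, against 88.6 (permutation p = 0.001). Runs of at least 4 such peaks numbered 1 for old (permutation p = 0.0659) and 5 for young (permutation p = 0.001). By number, 1 run of 4 or more is not beyond chance. The shuffles counted runs whatever their length, so they do not say how rare the run of 8 called peaks in old is. On chromosome 6, 24 of 25 tested peaks between 114445023 and 114587058 were higher in young, with a median log2 fold change of -0.99 and a median spacing of 2481 bp. On chromosome X, all 13 tested peaks between 72974922 and 73004777 were higher in young, with a median of -1.95 and a median spacing of 2528.5 bp. Whether these 2 runs are repeated sequence, in which the placement of reads is uncertain, was not tested for want of the mm9 sequence, so they are not given as separate changes in accessibility. Chromosome X held 60 of the peaks higher in young, or 5.79%, with the run of 13 among them, against 1.36% of peaks higher in old and 2.15% of those not called.

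The run higher in old lay on chromosome X at 7436290 to 7548993, with 8 of 11 tested peaks called. An equal gain over the region, as from an added copy, would give every peak 1 fold, but the folds differed by more than their errors (Cochran's Q p = 2.56e-05 over 11 peaks around a weighted mean of 1.36). Of the 2 peaks with the most counts, the one at 7475881 lay below the median of 1.43, at 0.42, and the one at 7524283 above it, at 2.13, although the bound set for this test had both below. The 5% of cells with the most counts in the region held 24.8%, 29.8% and 21.2% of its counts in old 1, old 2 and old 3. They held 22.4% and 20.4% in young 1 and young 2. These values argue against a gain held by 5% of old cells, but they cannot exclude a larger minority. Cells were ranked by counts not scaled for depth. A change in accessibility with age may account for the run and was not tested apart from the preparation of the sets.

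Narrow peaks under 300 bp with at least 2 counts per cell that had any formed a class of 314, defined after the widths and counts of the named peaks had been seen, so that its higher share in young cells restates that observation. They took 1.04% and 1.13% of counts in young 1 and young 2, against 0.291%, 0.314% and 0.260% in old 1, old 2 and old 3. Depth is argued against, since among cells of 5000 to 10000 counts the lowest young set was 3.02 times the highest old set. Across the cells of each set, which are not replicates, the shares of counts on alternate peaks of the class rose together, with Spearman's rho of 0.565 to 0.822 and Pearson's r of 0.483 to 0.920, or 0.526 to 0.831 without the 2 cells farthest from the median (permutation p = 1e-05 in each of the 5 sets, the smallest 100000 resamples can give), and rho was -0.199 to 0.107 for peaks matched on counts. This is what 1 source of reads shared by the class would give, such as a repeated sequence. The matched peaks were not matched on width or on counts per cell that had any, so other traits of such peaks were not tested. A candidate explanation for part of the peaks higher in young is that this source was more abundant in the young preparations, which cannot be told apart from age. Of the class, 90 peaks were tested and 48 were among the 1036 called higher in young. The limits of the class were chosen, so these 48 do not bound how many peaks such a source reaches. The peak at 66027197 on chromosome 2, for one, was 396 bp wide and held 4.26 counts per cell that had any. Whether peaks outside the class share the source was not tested.

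Cells of both ages also parted in clusters. Depth alone is argued against, since with thinned cells the largest difference in share was -65.2 percentage points. So are the called peaks alone, since without them it was -53.02, although peaks that differ with age but were not called remained. In thinned cells, leaving out the called peaks took the largest difference from -65.2 to -15.01, so depth and the called peaks together may account for most of it. The ages still did not overlap in 2 of the 4 clusters. Thinned cells leave less to cluster on, although with the called peaks they still parted by -65.2 points. A minority of old cells carrying the peaks higher in old, with the others like young cells, is argued against, since an old cell had more of these counts than a young cell in 90.5% or more of pairs for each old and young set, where under 50% of old cells could give at most 75%. The variance over cells, at 0.998, 1.13 and 1.44 times that of matched lists in old 1, old 2 and old 3, reached 1.5 in none, although in old 3 it was above the bound set beforehand for counting against a minority, so that test alone decides nothing.

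Of the 10 splits of the 5 sets into 2 and 3, 1 gave as many called peaks as the ages did, namely the ages themselves with 1844, and the highest of the others gave 9. So few splits cannot give a share under 0.05. Each of the other splits also puts sets of both ages in 1 group. A difference between the ages then adds to the spread within that group and lowers the calls. Their counts are therefore no measure of what chance gives.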
